A study of Mus musculus with 6 samples.

How the data were processed

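RNA was measured in 6 libraries of mouse embryonic fibroblasts with a floxed Brd4 gene, 3 labelled wild type (control) and 3 labelled BRD4 -/- (BRD4-deleted). Per the labels' protocols, cells were infected for 6 days with a retrovirus carrying Cre and GFP, sorted by flow cytometry, and total RNA was extracted with Trizol and made into libraries with an Illumina TruSeq RNA kit. The labels give this growth text for all 6 samples and do not say what the control cells received. They also do not say that replicates came from separate cultures or embryos, so the p-values measure the spread between these samples, which may be technical. Which exons are floxed is not given in the sources used here.

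The authors deposited raw counts per gene symbol, made with STAR alignment and HTSeq counting on the mm10 genome, per the submitters' processing notes. Tool versions, gene annotation, strand setting and read filters are not given in the sources used here. Each library holds counts for 24421 gene symbols. The summary lines that HTSeq adds were kept out of library sizes and tests: reads on no gene made up 12.6, 12.2 and 13.0% of all lines in control replicates 1, 2 and 3, and 12.7, 13.9 and 13.2% in BRD4-deleted replicates 1, 2 and 3. Reads on more than 1 gene made up 0.42 to 0.603%, and reads with more than 1 alignment 8.40 to 9.29%. Because HTSeq does not count reads with more than 1 alignment, genes with near-identical copies, such as histone and ribosomal protein genes, have uncertain counts. The 10 genes with the most counts took 9.00, 11.3 and 12.0% of the gene counts in the controls and 14.4, 12.2 and 12.0% in the BRD4-deleted libraries. With 38163802 to 58811810 gene counts per library, counting error is small beside the spread between libraries, except for genes under about 1 CPM.

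Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (13050 genes), library sizes were scaled by TMM (factors 1.04, 0.98, 1.02, 0.90, 1.01 and 1.04), and the groups were compared with glmQLFit (robust) and glmQLFTest, without covariates. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Fold changes are shrunk with a prior count of 0.125, and each standard error is the size of the unshrunk log2 fold change divided by the square root of its F statistic. The common dispersion gave a biological coefficient of variation of 25.7%. CPM values were computed here from the deposited counts with edgeR's cpm function on TMM-scaled library sizes.

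Gene lists were tested as sets with limma 3.58.1 (camera, preset correlation 0.01, on log2 CPM with a prior count of 2) and adjusted over the 39 lists with at least 5 tested members, out of 41. Beside each count of members past the threshold over all genes stands the count adjusted over the list alone. The grouping, the main test, the gene lists, the rule for named genes and the other settings, save 1 named below, were fixed before the data were examined. Named are, per direction, the 12 genes with the largest log2 fold change among those past the threshold with at least a 2-fold change, a mean of at least 5 CPM, no overlap between the groups and no predicted gene model as symbol. Also named are Brd4, Brd2, Brd3, Brdt, Myc, Hexim1, Serpini1 and Hist2h2be, and in each list up to 4 members of smallest adjusted p. Any other gene was chosen after its values were seen.

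Coordinates and overlaps between genes come from RefSeq on GRCm38.p6, the mm10 assembly, in which 24281 of the 24421 symbols were found. GC content and transcript length come from GENCODE M21 transcripts, which held 24027 symbols.

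The alternatives were DESeq2 size factors, library size alone and upper quartile scaling; no low-count filter, or at least 5 CPM in 3 libraries; the DESeq2 1.42.0 Wald test and limma-voom; the replicate number as a block; leaving out each library; leaving out the 10 most abundant genes; a glmTreat test of a change above 1.5-fold; and, for lists, camera with an estimated correlation and fry. Limma-voom with sample quality weights was added after the data were seen.

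The test was tried on simulated counts with the means and library sizes of the 13050 genes and 200 changed genes, for BRD4-deleted against control, 3 against 3. Of the 12929 genes kept, edgeR called 94, of which 8 (8.51%) were false, and it recovered 4.48% of genes changed 1.5-fold, 34.3% of those changed 2-fold and 90.9% of those changed 4-fold. DESeq2 recovered 19.4, 62.7 and 98.5% with 72 false among 192 calls (37.5%), and limma-voom 4.48, 32.8 and 89.4% with 10 false among 94 (10.6%). Changes of 1.5-fold were therefore mostly missed in this simulation. The data gave 2618 calls by edgeR's test, with unadjusted p up to 0.01, far more than the simulation. The shares recovered and false there need not hold for the data.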

Results

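Messenger RNA of mouse embryonic fibroblasts, connective tissue cells grown from mouse embryos, was sequenced in 6 libraries. All cells carried a floxed Brd4 gene, which Cre recombinase can excise. BRD4 is a bromodomain protein of the BET family that binds acetylated histones and takes part in transcription elongation. Of the 6 libraries, 3 were labelled wild type (control) and 3 BRD4 -/- (BRD4-deleted). The labels give infection with a retrovirus carrying Cre and GFP for all 6 samples. They do not say what the control cells received. Counts assigned to genes totalled 38163802, 56733069 and 58811810 in control replicates 1, 2 and 3. In BRD4-deleted replicates 1, 2 and 3 they totalled 56815369, 43485151 and 46754654. The series design compares transcript levels between cells with endogenous BRD4 and cells in which it was deleted. Log2 changes below are BRD4-deleted minus control, with standard errors (SE) from edgeR's quasi-likelihood test over 3 libraries per group, and adjusted p-values are Benjamini-Hochberg values of that test. CPM is edgeR's unit of counts scaled to the normalised library size, given as mean and SD over 3 libraries. Coordinates refer to GRCm38 (mm10).

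Brd4 itself fell to 80.1% of its control level (95% confidence interval 69.5 to 92.4%). Its level was 114, 113 and 112 CPM in control replicates 1, 2 and 3, and 84.4, 95.5 and 91.2 CPM in the BRD4-deleted replicates. Its log2 change was -0.32 (SE 0.09, adjusted p = 0.0453, edgeR's quasi-likelihood test). The gene lies on chromosome 17 from 32196272 to 32284743. Its family member Brd2 rose, with a log2 change of 0.95 (SE 0.24, adjusted p = 0.0385), from 239 ± 31.6 to 461 ± 135 CPM. Brd3 (log2 change -0.23, adjusted p = 0.131) and the testis gene Brdt (-0.36, adjusted p = 0.606) did not pass the test. The gene-level count holds reads from all exons, so it cannot show whether the floxed part was removed, and the labels do not name that part. The Brd4 call was lost in each of the 6 fits that left out 1 library, with log2 changes from -0.36 to -0.27 and adjusted p from 0.0504 to 0.129. It was also lost with library size scaling (adjusted p = 0.0906), with upper quartile scaling (0.0556) and without a low-count filter (0.0609). Leaving out any library but BRD4-deleted replicate 1 ended the Brd2 call, with log2 changes over the 6 fits from 0.80 to 1.17 and adjusted p from 0.0029 to 0.125.

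**Figure D1:**
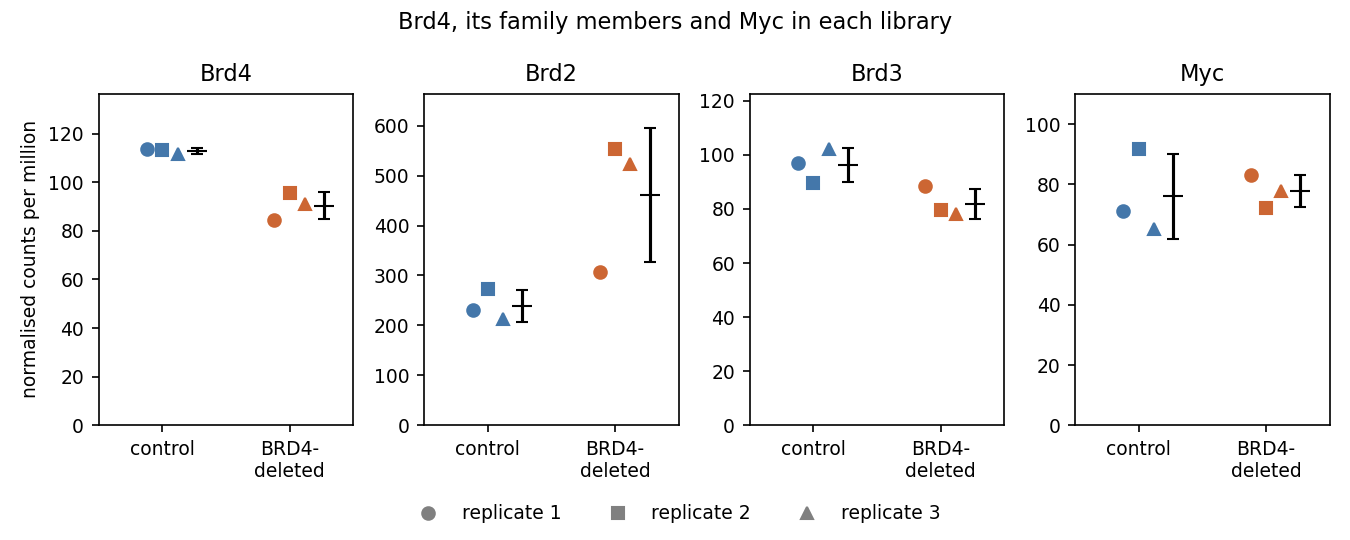
Normalised counts (CPM) of Brd4, Brd2, Brd3 and Myc in each library, with each group's mean and SD over 3 libraries. Brd4 sits between 112 and 114 CPM in the controls and between 84.4 and 95.5 CPM in the BRD4-deleted libraries, and each gene has its own axis from 0.

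Genes used elsewhere as markers of the response to BET inhibitors moved in both directions. Hexim1, which encodes an inhibitor of the elongation kinase P-TEFb, fell from 29.2 ± 1.71 to 18.5 ± 2.72 CPM (log2 change -0.66, SE 0.13, adjusted p = 0.0236). Serpini1 rose from 1.05 ± 0.153 to 2.85 ± 0.795 CPM (log2 change 1.44, SE 0.29, adjusted p = 0.0238). Hist2h2be, a histone H2B gene with a polyadenylated transcript, rose from 0.892 ± 0.21 to 3.67 ± 0.484 CPM (log2 change 2.03, SE 0.26, adjusted p = 0.0111). Myc had 76.0 ± 14.0 CPM in control and 77.8 ± 5.41 CPM in BRD4-deleted cells, a log2 change of 0.03 (SE 0.15, adjusted p = 0.887). The Myc value changed sign with library size scaling (-0.01) and in the fits without control replicate 1 (-0.01), control replicate 3 (-0.07) or BRD4-deleted replicate 1 (-0.02). Hist2h2be passed in all 6 fits that left out 1 library. Hexim1 passed in 1 of them, the fit without BRD4-deleted replicate 1 (adjusted p from 0.00459 to 0.074 over the 6). Serpini1 passed in 2 and lost its call without control replicate 1, 2 or 3 or BRD4-deleted replicate 3 (adjusted p from 0.0252 to 0.0803 over the 6).

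Over all 13050 genes tested, 1379 rose and 1239 fell in BRD4-deleted cells, together 20.1% of the tested genes. Of these, 1030 changed at least 2-fold, of which 459 rose and 571 fell. Among the 12 largest rises under the naming rule were those of Igf2 and H19, a fetal growth factor gene and its neighbouring non-coding RNA, both imprinted. Igf2 (chromosome 7, 142650768 to 142666816) rose from 0.364 ± 0.191 to 41.7 ± 33.3 CPM, a log2 change of 6.80 (SE 0.77, adjusted p = 0.00993). H19 (chromosome 7, 142575530 to 142578146) rose from 4.08 ± 2.22 to 137 ± 99.0 CPM, a log2 change of 5.08 (SE 0.71, adjusted p = 0.0132). The metallothionein genes Mt2 and Mt1, which encode metal-binding proteins and lie side by side on chromosome 8, rose with log2 changes of 5.11 (SE 0.69, adjusted p = 0.0126) and 3.71 (SE 0.38, adjusted p = 0.00862). Mt1 rose from 11.4 ± 3.56 to 150 ± 59.4 CPM and Mt2 from 3.49 ± 2.39 to 122 ± 53.7 CPM. The other genes of the 12 largest rises were Apoe (4.07), a lipid transport protein gene, Sdk1 (3.52), H2-DMa (3.51), the linker histone gene Hist1h1d (3.41), Fgf18 (3.39), the basement membrane collagen gene Col4a6 (2.59), Sema3b (2.59) and the histone H4 gene Hist1h4i (2.54), with adjusted p from 0.00918 to 0.0359.

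The 12 largest falls under the same rule included that of Acan, the proteoglycan of cartilage, which fell from 79.96 ± 51.3 to 5.64 ± 3.31 CPM (log2 change -3.82, SE 0.71, adjusted p = 0.02). Col6a3 (chromosome 1, 90766860 to 90844001), which encodes a chain of collagen VI, fell from 1126 ± 228 to 118 ± 117 CPM (log2 change -3.26, SE 0.88, adjusted p = 0.0475). Smoc2, a secreted calcium-binding matrix protein gene, fell from 133 ± 19.9 to 15.2 ± 5.28 CPM (log2 change -3.12, SE 0.27, adjusted p = 0.00657). Plk1, a kinase of mitosis, fell with a log2 change of -3.03 (SE 0.48, adjusted p = 0.0152), and Cdh3, which encodes P-cadherin, with one of -3.00 (SE 0.27, adjusted p = 0.00657). The other 7 were Mrvi1 (-3.91), Ldb3 (-3.45), Glipr1 (-3.29), Myct1 (-3.21), the DNA helicase gene Pif1 (-3.08), Fam84b (-2.98) and Tmem119 (-2.93), with adjusted p from 0.0105 to 0.0254. All 3 BRD4-deleted libraries lay on one side of all 3 controls for each of these 24 genes, which the naming rule required. Over all tested genes this held for 5995 (45.9%), while a single gene with no group difference would do so with a chance of 10%. Genes are not independent replicates, so the share over genes does not show what chance alone would give.

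The counts of calls depended on which libraries were in the fit. Without control replicate 1, 2 or 3, the test called 623, 447 and 964 genes, and without BRD4-deleted replicate 2 or 3 it called 646 and 717, against 2618 in all. Without BRD4-deleted replicate 1 it called 3612, of which 2443 were among the 2618. At an unadjusted p under 0.05 these 6 fits gave 3917 to 5515 genes, against 4895 with all libraries. Of the 2618 genes, 314 passed in all 6 of these fits, 157 higher and 157 lower, and 65.0% had an adjusted p of 0.02 or more. Igf2, Mt1, H2-DMa, Hist1h4i, Ldb3, Glipr1, Smoc2, Cdh3 and Tmem119 were the 9 of the 24 genes of largest change that passed in all 6. Over the 6 fits the log2 change of Igf2, at 80.05 CPM in BRD4-deleted replicate 1 against 25.01 and 20.06 CPM in replicates 2 and 3, ran from 5.90 to 7.28. Other wide ranges were those of H19 (4.34 to 5.59), Apoe (3.31 to 4.58), Sdk1 (2.80 to 3.99), Fgf18 (2.45 to 4.19), Sema3b (1.75 to 2.90), Mrvi1 (-5.03 to -3.50), Acan (-4.42 to -3.32), Col6a3 (-4.40 to -2.75) and Myct1 (-4.27 to -2.81). H19 missed the threshold without control replicate 2 (adjusted p = 0.0524), as did Mt2 (0.0517), and Col6a3 did so without control replicate 1, 2 or 3 or BRD4-deleted replicate 3, with adjusted p up to 0.128. Some gene spans, introns included, overlap: Brd2 with H2-DMa, Igf2 with Igf2os and Mir483, H19 with Mir675 and Brd4 with Gm4432. Mrvi1, Glipr1, Smoc2 and Fam84b overlap with their own neighbours. Reads on more than 1 gene were kept out of the counts. Without a stated strand setting, how far these overlaps affect the counts of each gene cannot be told.

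**Figure D2:**
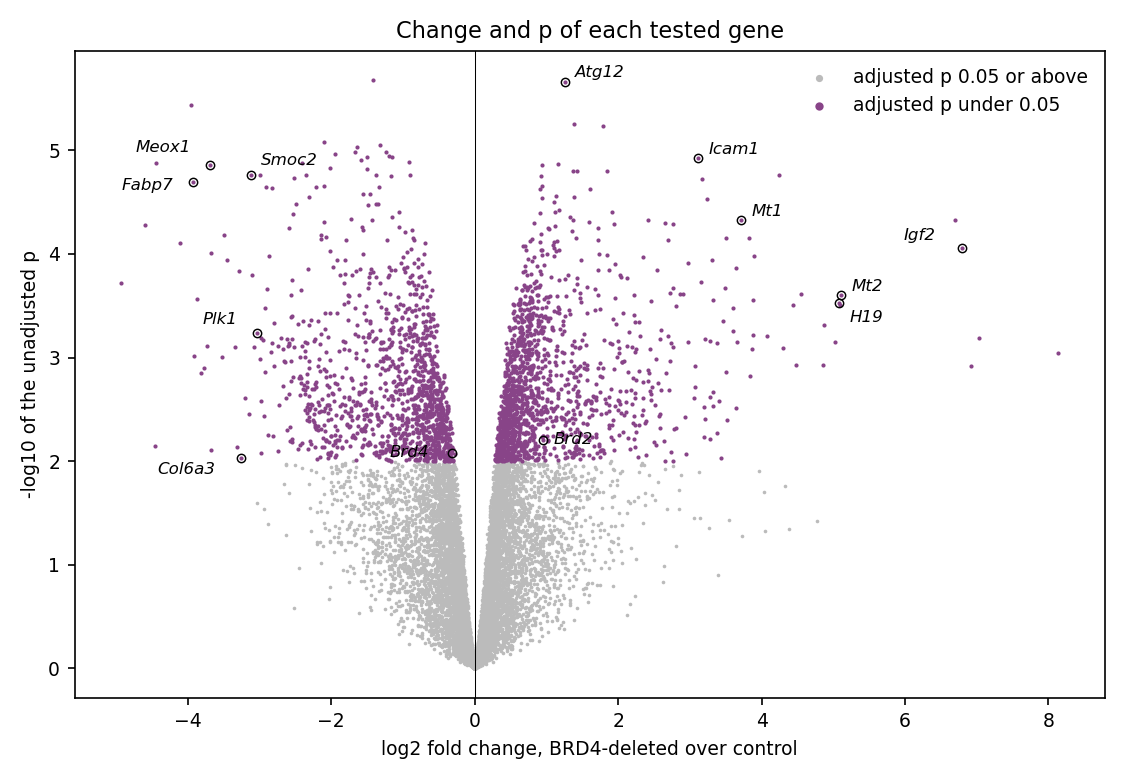
Each point is 1 of 13050 tested genes, with its log2 fold change on the horizontal axis and -log10 of its unadjusted p from edgeR's quasi-likelihood test on the vertical axis, over 3 BRD4-deleted and 3 control libraries. Igf2 lies at 6.80 and Col6a3 at -3.26 on the horizontal axis, and Brd4 lies at -0.32, close to the boundary of adjusted p 0.05.

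Of 41 gene lists, 39 had at least 5 tested members, and 11 differed from the other genes by limma's camera test with a preset correlation of 0.01. By that test the lists of autophagy and lysosomes, of histones and of the immediate early response were higher as sets. The immediate early list had a median of 1.88 in BRD4-deleted replicate 1 against 0.28 and 0.06 in replicates 2 and 3. The lists of G2 and mitosis, S phase, DNA repair, splicing and ribosomal proteins were lower as sets. So were those of contractility, chromatin regulators and MYC targets with ribosome biogenesis. Each of the 11 lists had adjusted p = 0.94 with an estimated correlation, where the smallest unadjusted p over all 39 lists was 0.0616. Other groupings of the same 6 libraries, 3 against 3, gave from 9 to 18 lists by the same test, so the number 11 is not particular to the grouping by BRD4. The other groupings gave no gene past edgeR's adjusted threshold. At an unadjusted p under 0.05 they gave 35 to 698 genes, against 4895 in the real one. Each of them mixes control and BRD4-deleted libraries, which puts any difference between the real groups into the spread within groups. Few calls are therefore built in, and these gene counts do not show what chance alone would give.

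Of 37 tested genes of G2 and mitosis, 35 fell and 2 did not pass the test, with a median log2 change of -2.24. Examples are Plk1, the cytokinesis gene Anln (log2 change -2.54, SE 0.37, adjusted p = 0.0138), the ubiquitin-conjugating enzyme gene Ube2c (-2.59, SE 0.43, adjusted p = 0.0157) and the centromeric histone gene Cenpa (-2.37, SE 0.39, adjusted p = 0.0157). All 37 fell adjusted over the list alone, and the camera test of the list gave adjusted p = 1.78e-14. Against the control mean the list's median was -3.42, -2.09 and -1.64 in BRD4-deleted replicates 1, 2 and 3, and 0.44, -0.55 and 0.11 in control replicates 1, 2 and 3. The number of members that fell by edgeR's test was 3, 11 and 7 without control replicate 1, 2 or 3, and 37, 0 and 22 without BRD4-deleted replicate 1, 2 or 3. In those 6 fits 36 or 37 members had an unadjusted p under 0.05, and the median ran from -2.62 to -1.90.

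Of 41 tested S phase and replication genes, 3 fell, which were Rrm1 (log2 change -1.45, SE 0.32, adjusted p = 0.0292) and Tyms (-1.59, SE 0.38, adjusted p = 0.0343), both enzymes of nucleotide synthesis, and Pcna (-1.14, SE 0.31, adjusted p = 0.0458), the sliding clamp of replication. The list's median was -0.96 and the camera test gave adjusted p = 4.50e-06. Adjusted over the list alone, edgeR's test called 0 members, with 7 lower at an unadjusted p under 0.05, and DESeq2 called 10 lower over all genes. Of 33 DNA damage response and repair genes, 5 fell, which were Nbn (-0.85), Blm (-1.65), Xrcc5 (-0.66), Atm (-0.48) and Xrcc2 (-1.20, named after its value was seen), with adjusted p from 0.0153 to 0.0494. The list held 4 falls adjusted over the list alone, the median was -0.66 and the camera test gave adjusted p = 7.06e-05. BRD4-deleted replicate 1 stood apart in both lists. The S phase median was -2.73 in that library against -0.70 and -0.42 in replicates 2 and 3, and the repair median was -1.40 against -0.52 and -0.51. Without it, 33 S phase genes fell and 1 rose around a median of -0.55, and 18 repair genes fell and 1 rose around a median of -0.55. Leaving out any of the other 5 libraries instead left 0 S phase genes past the threshold (4 to 14 lower at an unadjusted p under 0.05) and at most 2 repair genes (6 to 20).

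**Figure D3:**
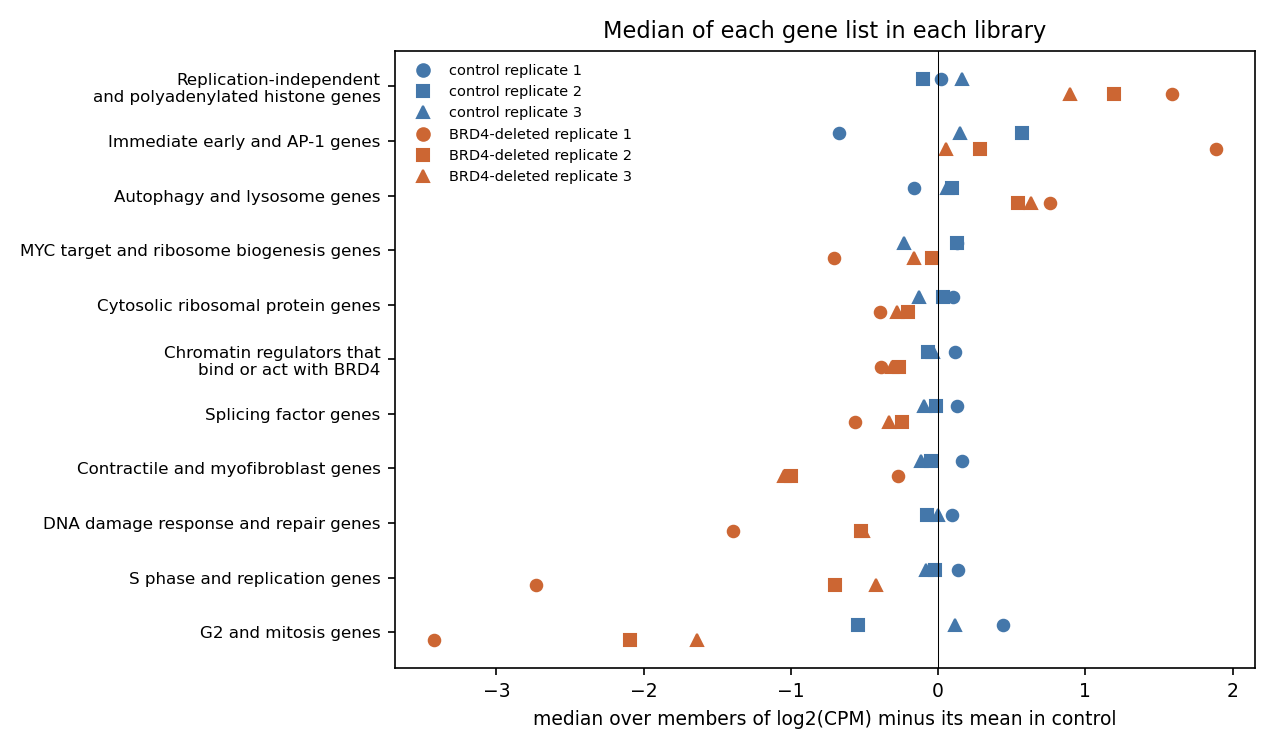
For each of the 11 gene lists past the camera test, the median over members of log2 CPM minus its control mean is drawn for each control library (blue) and each BRD4-deleted library (orange), with circles, squares and triangles for replicates 1, 2 and 3. The G2 and mitosis list sits at -3.42, -2.09 and -1.64 in the BRD4-deleted libraries, and the immediate early list is at 1.88 in BRD4-deleted replicate 1 against 0.28 and 0.06 in replicates 2 and 3.

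Of 40 tested autophagy and lysosome genes, 22 rose and 18 did not pass, with a median log2 change of 0.62. Examples are Atg12 (1.25, SE 0.08, adjusted p = 0.00657), which encodes a ubiquitin-like protein of autophagosome formation, the lysosomal enzyme gene Gns (1.30, SE 0.17, adjusted p = 0.0111), Tecpr1 (0.88, SE 0.12, adjusted p = 0.0126) and the lysosomal membrane protein gene Lamp1 (1.06, SE 0.15, adjusted p = 0.0126). There were 30 rises and 1 fall adjusted over the list alone, and the camera test gave adjusted p = 3.28e-09. The medians of BRD4-deleted replicates 1, 2 and 3 against the control mean were 0.76, 0.54 and 0.63. The number that rose was 8, 7 and 9 without control replicate 1, 2 or 3, and 22, 11 and 8 without BRD4-deleted replicate 1, 2 or 3. Atg12, Gns and Tecpr1 passed in all 6 of these fits.

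Of 17 tested replication-independent and polyadenylated histone genes, 10 rose and 1 fell, around a median of 1.24. The rises included Hist3h2a (log2 change 1.91, SE 0.20, adjusted p = 0.0083), Hist1h2be (2.90, SE 0.41, adjusted p = 0.0126), Hist1h4i and Hist2h2be, and the fall was that of the H2A.Z gene H2afz (-1.25, named after its value was seen). Adjusted over the list alone 10 rose and 2 fell, and the camera test gave adjusted p = 0.00329. Hist1h2be, Hist1h4i and Hist2h2be had under 10 CPM in both groups, and histone genes have near-identical relatives, so the reads assigned to each are uncertain. The camera call was lost when only genes of at least 5 CPM in 3 libraries were kept (adjusted p = 0.14), where 6 of 13 rose and the median was 0.22, so the median of 1.24 rests on members with few reads. The number that rose was 7, 4 and 5 without control replicate 1, 2 or 3, and 9, 5 and 7 without BRD4-deleted replicate 1, 2 or 3, and Hist3h2a, Hist1h4i and Hist2h2be passed in all 6.

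Of 31 tested immediate early and AP-1 genes, which cells induce within minutes of a stimulus, 2 rose: Ier3 (log2 change 1.44, SE 0.28, adjusted p = 0.0219) and Jund (1.38, SE 0.27, adjusted p = 0.0237). Adjusted over the list alone 2 rose as well, the median was 1.11 and the camera test gave adjusted p = 0.0357. The list's median was 1.88 in BRD4-deleted replicate 1 and 0.28 and 0.06 in replicates 2 and 3, and -0.67, 0.57 and 0.15 in the controls. The camera call was lost without BRD4-deleted replicate 1 (median 0.07, adjusted p = 0.626), control replicate 1 (0.214) or control replicate 3 (0.0954), and with limma-voom and sample quality weights, which were added after the data were seen (0.619). Fosb, a subunit of AP-1, had 394 CPM in BRD4-deleted replicate 1 and 8.78 and 4.36 CPM in replicates 2 and 3, and the nuclear receptor gene Nr4a1 had 1262 against 33.7 and 33.1 CPM. Atf3 (log2 change 4.77, adjusted p = 0.111) had 633 against 11.3 and 13.2 CPM. Fosb, Nr4a1 and Egr3 are named here after their values were seen.

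**Figure D4:**
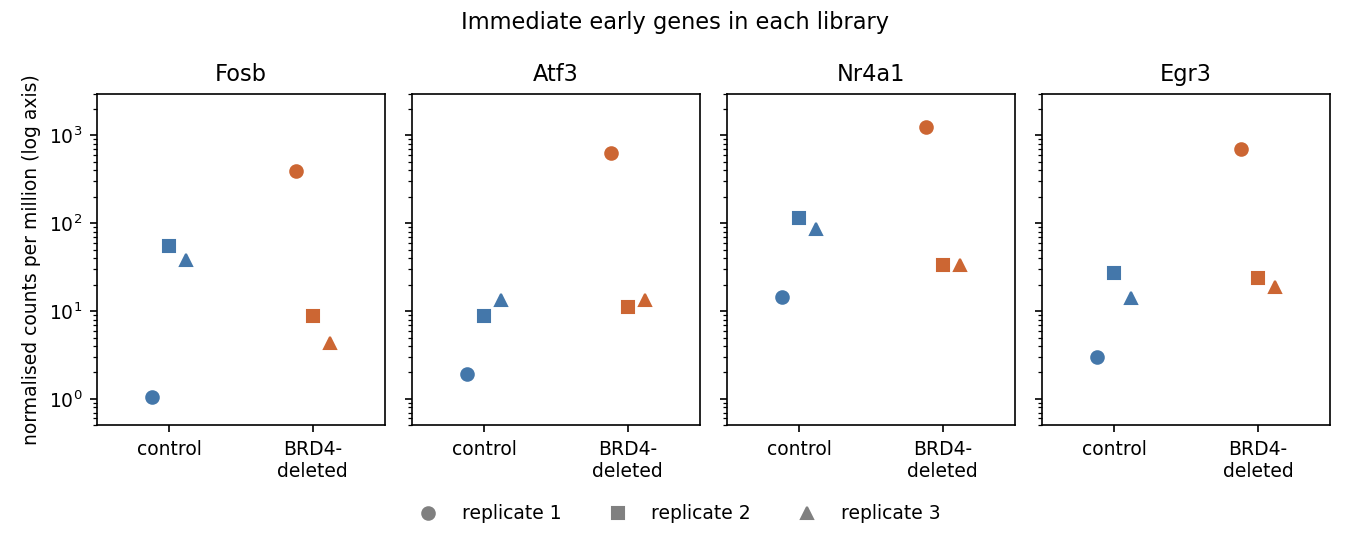
Normalised counts (CPM) of Fosb, Atf3, Nr4a1 and Egr3 in each library on a log axis. BRD4-deleted replicate 1 has 394, 633, 1262 and 692 CPM of these genes, above each of the other 5 libraries.

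Of 44 tested splicing factor genes, 17 fell and 27 did not pass, around a median of -0.36 (24 fell adjusted over the list alone, camera adjusted p = 5.85e-08). Examples are the RNA-binding protein genes Fus (log2 change -0.99, SE 0.13, adjusted p = 0.0111), Sfpq (-0.90, SE 0.13, adjusted p = 0.0126), Srsf3 (-0.66, adjusted p = 0.0153) and Ptbp1 (-0.79, adjusted p = 0.018). Of 53 cytosolic ribosomal protein genes, 11 fell and 1 rose (Rpl22, 0.34, named after its value was seen), around a median of -0.29, with Rpl10a (-0.58), Rps3 (-0.60), Rps4x (-0.58) and Rps5 (-0.45) of smallest adjusted p. With p-values adjusted over the list alone 13 fell and 1 rose, and the camera test gave adjusted p = 5.30e-08. These genes have many processed pseudogenes, so their counts are uncertain. Of 31 chromatin regulators that bind or act with BRD4, 6 fell, among them the Polycomb gene Eed (-0.67), the cohesin gene Rad21 (-0.79), the insulator protein gene Ctcf (-0.42) and the deacetylase gene Hdac2 (-0.35). Adjusted over the list alone 13 fell, the median was -0.33 and the camera test gave adjusted p = 0.00185. Of 40 MYC target and ribosome biogenesis genes, Nop58 (-0.72, adjusted p = 0.0447) and Tcof1 (-0.66, adjusted p = 0.0474) fell, around a median of -0.26 (camera adjusted p = 0.00553). Adjusted over this list alone edgeR's test called 0 members, with 9 lower at an unadjusted p under 0.05, and DESeq2 called 7 lower over all genes. The camera call of the MYC target list was lost without BRD4-deleted replicate 1 (adjusted p = 0.358) or control replicate 2 (0.0554), and with the same sample quality weights (0.0805).

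Of 31 contractile and myofibroblast genes, 8 fell and 23 did not pass, around a median of -0.62. They included the tropomyosin genes Tpm4 (log2 change -0.88, SE 0.18, adjusted p = 0.023) and Tpm2 (-0.93, SE 0.19, adjusted p = 0.0238), the smoothelin gene Smtn (-0.62, adjusted p = 0.0234) and the integrin gene Itga5 (-1.10, adjusted p = 0.0239). Falls adjusted over the list alone numbered 10, and the camera test gave adjusted p = 5.73e-04. BRD4-deleted replicate 1 had a median of -0.27 against -1.0 and -1.05 in replicates 2 and 3, and without it 23 of these genes fell and 1 rose, around a median of -1.04. Of the splicing genes 3, 3 and 4 fell without control replicate 1, 2 or 3, and 18, 3 and 2 without BRD4-deleted replicate 1, 2 or 3, and Fus and Sfpq passed each time. Of the chromatin regulators 10 fell without BRD4-deleted replicate 1 and 1 without any other library. Without BRD4-deleted replicate 1, 9 ribosomal protein genes and 5 MYC targets fell. Without each of the other libraries, edgeR's test called at most 3 ribosomal protein genes (13 to 31 lower at an unadjusted p under 0.05), at most 2 contractile genes (10 to 12) and 0 MYC targets (2 to 12).

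Extracellular matrix genes that fell included several chains of collagen. Of 49 tested, 8 fell and 41 did not pass: the collagen genes Col12a1 (log2 change -1.44, SE 0.18, adjusted p = 0.0111), Col6a2 (-2.32, SE 0.29, adjusted p = 0.0111), Col6a1 (-1.23, SE 0.18, adjusted p = 0.0135), Col6a3 and Col18a1, the fibromodulin gene Fmod (-3.88, SE 0.55, adjusted p = 0.0127), and Mfap5 and Loxl3. Col12a1 went from 2885 ± 571 to 1060 ± 93.8 CPM, and the 3 collagen VI genes each fell, Col6a1 passing in 5 of the 6 fits that left out 1 library and Col6a3 in 2. As a set the list did not pass (median -0.17, camera adjusted p = 0.172), and 7 members fell adjusted over the list alone. The camera test passed without BRD4-deleted replicate 1 (median -0.46, adjusted p = 0.012) or control replicate 1 (median -0.25, adjusted p = 0.00563). Col12a1, Col6a2, Fmod (-4.18 to -3.28) and Col18a1 passed in all 6 fits that left out 1 library. Of 14 cartilage and bone markers, 4 fell alongside these: Acan, Col2a1 (-2.07), Matn3 (-2.43) and Spp1 (-1.65), with a camera adjusted p of 0.121. Col2a1, the collagen of cartilage, had 312 ± 91.4 CPM in control and 74.6 ± 32.4 CPM in BRD4-deleted cells. Of 24 matrix proteases and inhibitors, the plasminogen activator gene Plat rose (2.04, SE 0.26, adjusted p = 0.0112), as did Timp2 (0.87), and the other activator gene Plau fell (-1.61, SE 0.33, adjusted p = 0.0245).

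None of the lists of stress and cell fate passed the camera test, and most held members that moved both ways. Of 30 p53 targets 4 rose, Rrm2b (0.45), Gdf15 (1.92), Zmat3 (0.52) and Mdm2 (0.71), and Gtse1 (-1.29) and Ckap2 (-1.86), which also act in mitosis, fell (camera adjusted p = 0.194). Of 21 apoptosis regulators the inhibitor gene Cflar (0.89), Casp9 (0.53) and Bcl2l11 (0.95) rose, while Bok (-1.55), Bcl2 (-1.03), Bak1 (-0.70), Birc3 (-0.63) and Cycs (-0.66) fell (0.544). Of 23 senescence-associated genes 6 rose and 7 fell, with Glb1 (0.95) and Plat among the rises and Hmgb1 (-1.0) and Cdkn2c (-1.12) among the falls (0.857). Of 26 NF-kB and inflammatory genes the adhesion molecule gene Icam1 (3.11), the cytokine genes Csf1 (1.35) and Cxcl10 (3.33) and the complement gene C3 (2.52) rose, and Cxcl12 (-1.01) and Birc3 fell (0.268). Of 32 interferon-stimulated genes Tap1 (0.86) and Ifit1 (3.43) rose (0.0755), with 10 higher at an unadjusted p under 0.05 and 11 higher by DESeq2 over all genes. Ifit1 had 10.1 CPM in BRD4-deleted replicate 1 against 2.32 and 0.86 CPM in replicates 2 and 3. Ifit1 and Tap1 each passed in 2 of the 6 fits that left out 1 library, with log2 changes of Ifit1 from 1.94 to 3.91 and adjusted p up to 0.138, and Cxcl10 passed in 2 as well (2.47 to 3.69). Of 31 unfolded protein and integrated stress response genes Pdia4 (0.66) and Ddit3 (2.34) rose, and Mthfd2 (-1.16) and Xbp1 (-0.77) fell (0.857). Of 27 NRF2 and oxidative stress genes 5 rose, Mt1, Mt2, the ferritin gene Ftl1 (1.03), Hmox1 (1.25) and Srxn1 (0.65) (0.672). Icam1, Bok, Glb1, Plat, Hmgb1 and Mt1 passed in all 6 fits that left out 1 library. Zmat3, Mdm2, Casp9, Bcl2l11, Birc3, Cycs, C3 and Srxn1 are named after their values were seen, as are Col18a1, Mfap5 and Loxl3 of the matrix list.

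In the lists of metabolism, 6 oxidative phosphorylation genes of 40 rose, among them Ndufa1 (0.62) and Ndufb10 (0.51), and 2 fell, Atp5g1 (-0.38) and Cycs (camera adjusted p = 0.407). Of 30 glycolysis and hypoxia genes Bnip3l (1.09), Ero1l (0.88) and Pdk1 (1.69) rose and Ankrd37 (-1.26) fell (0.857). Of 25 cholesterol synthesis genes Pcsk9 (-1.54), Stard4 (-1.06) and Dhcr7 (-0.63) fell (0.172), and of 24 fatty acid and lipid droplet genes Lpin1 (0.97) rose and Acsl5 (-1.34) fell (0.403). In the signalling lists, the receptor genes Tgfbr2 (1.15) and Tgfbr3 (1.96) and Smad3 (0.78) rose and Ltbp4 (-1.64), Bambi (-2.05) and Inhba (-0.82) fell among 30 TGF-beta pathway genes (0.861). Of 29 growth factor and receptor genes Igf2, Fgfr1 (0.80), Areg (1.69) and Met (0.76) rose (0.737), and of 18 imprinted growth genes Igf2, H19, Impact (1.10) and Peg10 (1.75) rose (0.268). Of 22 YAP and TEAD targets Ptpn14 (0.82) rose and Amotl1 (-0.33) fell (0.857). Of 27 P-TEFb and elongation factor genes Hexim1 and Hexim2 (-1.59) fell (0.861), and of 32 Mediator genes Med14 (-0.65) and Med12 (-0.51) fell (0.732). Of 16 Hox genes edgeR's test called 0, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom (0.861). The Amotl1 call was lost in each fit that left out 1 library (adjusted p from 0.0507 to 0.143), and Ptpn14 passed in 1 of the 6. Acsl5, Bnip3l, Ero1l, Tgfbr2, Tgfbr3, Fgfr1 and Impact passed in all 6 fits that left out 1 library, and Atp5g1, Smad3 and Inhba are named after their values were seen.

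Markers of cell types other than fibroblasts were mostly low. Of 15 tested fibroblast and mesenchyme markers Pdpn rose (1.72, SE 0.19, adjusted p = 0.00864) and the transcription factor gene Meox1 fell (-3.69, SE 0.32, adjusted p = 0.00657), while Vim had 3498 ± 229 CPM in control and 4831 ± 140 CPM in BRD4-deleted cells (adjusted p = 0.053). Of 5 macrophage markers Cd68 rose (1.22), and of 6 epithelial markers Krt15 (5.02) and Cldn4 (2.66) rose and Krt19 (-1.28) fell. Of 7 adipocyte markers Fabp4 (-1.81) and Pparg (-2.07) fell, of 8 neural and glial markers Fabp7 fell (-3.93, SE 0.37, adjusted p = 0.00675), and of 8 skeletal muscle markers Tnni1 fell (-2.12). Of 8 endothelial markers edgeR's test called 0, with 1 higher and 2 lower at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Camera adjusted p-values of these lists ran from 0.407 (neural) and 0.63 (endothelial) through 0.744 (epithelial), 0.857 (fibroblast) and 0.861 (muscle) to 0.87 (macrophage, adipocyte). Krt15, Cldn4, Cd68, Tnni1 and Fabp7 had under 3 CPM in both groups, and Meox1, Pdpn and Fabp7 passed in all 6 fits that left out 1 library. Cldn4 passed in 0 of those fits (log2 change from 2.24 to 3.86, adjusted p from 0.053 to 0.135), Krt19, Cd68 and Tnni1 in 1 and Krt15 in 3 (log2 change from 4.08 to 5.33). Xist had 240 ± 75.8 and 187 ± 20.7 CPM (log2 change -0.36, adjusted p = 0.288), and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had a count of 0 in all 6 libraries.

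Over the 30 lists not called by camera, 100 of 605 distinct tested genes changed, 50 higher and 50 lower. This is a smaller share than the 20.1% of all tested genes that changed. The changes named in these lists are therefore no more frequent than among genes in general. Without control replicate 1, 2 or 3 the number of changed genes in these lists was 39, 29 and 46. Without BRD4-deleted replicate 1, 2 or 3 it was 157, 35 and 41. The camera test of a list also turned positive for interferon-stimulated genes without BRD4-deleted replicate 2 (0.00826) or 3 (8.11e-04), NF-kB genes without BRD4-deleted replicate 3 (0.0168), p53 targets without BRD4-deleted replicate 2 (0.0305), cholesterol genes without BRD4-deleted replicate 1 (0.025) or control replicate 3 (0.0241), and oxidative phosphorylation genes and cartilage markers without BRD4-deleted replicate 1 (0.0498 each). Among the other settings, the interferon list passed with library size scaling (0.0259), without a low-count filter (0.00265), with DESeq2 (0.0125) and with the replicate block (0.0362). Imprinted genes passed with DESeq2 (0.0168), cholesterol genes with the replicate block (0.0304) and with sample quality weights (0.032), and matrix genes with those weights (0.013). DESeq2 also called more members over all genes: 9 p53 targets, 8 NF-kB genes and 7 matrix genes were higher by it, and 11 matrix, 14 chromatin regulator, 15 repair, 15 contractile and 22 ribosomal protein genes were lower. The interferon list's median was 1.81 in BRD4-deleted replicate 1 and 0.32 and 0.02 in replicates 2 and 3. Median, mean and camera direction differed in sign for the lists of P-TEFb, matrix proteases, glycolysis, the unfolded protein response, growth factors, Hox genes and fibroblast, macrophage, muscle and adipocyte markers, none of which passed.

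The libraries of each group were not equally alike. BRD4-deleted replicate 1 differed from the mean of the other replicates of its group by an SD of 0.79 on the log2 scale over genes, against 0.37 to 0.50 for the other 5 libraries. The first principal component held 57.1% of the variance and parted the groups, with the controls from -53.4 to -35.4. BRD4-deleted replicate 1 lay at 67.65 on it, and replicates 2 and 3 at 32.3 and 28.3. The second component held 24.4% and placed BRD4-deleted replicate 1 at -44.9 and replicates 2 and 3 at 35.3 and 35.4. Among genes of at least 5 CPM, 54 differed at least 8-fold between BRD4-deleted replicate 1 and the mean of replicates 2 and 3. Col6a3 had 17.8 CPM in that library against 247 and 88.1 CPM. No pair of libraries agreed within sampling noise: the smallest chi-square per degree of freedom over genes was 41.1, between BRD4-deleted replicates 2 and 3.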

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

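Limma-voom with sample quality weights was chosen after the data were seen; the other alternatives were planned. No gene called by edgeR's quasi-likelihood test changed sign under any alternative, and the other scalings moved the median of all genes by no more than library size alone did (-0.0414 on the log2 scale). The number of calls was less stable. Against 1379 higher, 1239 lower and 1030 changed at least 2-fold, the 6 fits that left out 1 library gave 212 to 1655 higher, 235 to 1957 lower and 286 to 1265 at least 2-fold. The lowest counts came without control replicate 2 and the highest without BRD4-deleted replicate 1, and fits with fewer samples have less power. Sample quality weights gave 2326 higher and 2351 lower, with a weight of 0.224 for BRD4-deleted replicate 1 against 2.34 and 2.42 for replicates 2 and 3. DESeq2 called 1944 lower and 3940 genes in all. In the simulation 37.5% of its 192 calls were false, a share that need not hold for the data. The fit with a filter of 5 CPM in 3 libraries, which tests fewer genes (9971), called 572 genes changed at least 2-fold, and the glmTreat test of a change above 1.5-fold called 155 genes in all.

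With the replicate number as a block, the calls were 18 higher, 34 lower and 52 at least 2-fold, and Brd4 had -0.32 (adjusted p = 0.129). At an unadjusted p under 0.05 of edgeR's test the block fit gave 4064 genes, against 4895 in the main fit. The block leaves fewer degrees of freedom, so this fit has less power. The replicate numbers are not known to pair the samples. Deviations from the group means correlated at -0.23, 0.224 and -0.191 for equal numbers. The highest correlation, 0.372, was between control replicate 3 and BRD4-deleted replicate 1.

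Brd4 stayed lower but missed the threshold with library size scaling (-0.36), upper quartile scaling (-0.32), no low-count filter (-0.33) and each library left out (-0.36 to -0.27); adjusted p over all alternatives in which the call was lost ran from 0.0504 to 0.129. The cause was not tested. Of the 11 lists past camera, 0 passed with an estimated correlation (0 at an unadjusted p under 0.05), and fry passed 2 of them, histone genes (adjusted p = 0.0267) and autophagy and lysosome genes (0.04). Outside the 11, fry passed neural and glial markers (0.04). Reversed values were those of Brdt without control replicate 3 (range over the 6 fits -0.69 to 0.12), Csf1r without BRD4-deleted replicate 2 (-0.026 to 0.65), and Myc without control replicate 1 or 3 or BRD4-deleted replicate 1 (-0.069 to 0.19), with library size scaling (-0.0073) and with quality weights (-0.051); none of the 3 genes passed the test, and the cause was not tested. Over the 177 named genes and all alternatives, 2196 values kept their direction and side of the threshold, 538 lost the threshold, 55 gained it and 7 reversed. For the 11 lists, 170 values kept both and 28 lost the threshold.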

Other observations

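The other splits of the libraries and the fits that left out 1 library were planned. The remaining tests in this part were chosen after the pattern they bear on had been seen. What each should show is recorded as set down before its own result was known. For the S phase and Hox lists that order cannot be shown, since their values came from the same run as the patterns. The elastin gene Eln varied within both groups: it had 1.61, 328 and 287 CPM in control replicates 1, 2 and 3, and 103, 3.59 and 1.19 CPM in BRD4-deleted replicates 1, 2 and 3 (adjusted p = 0.400, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The oxidative stress gene Nqo1 had 8.17 CPM in BRD4-deleted replicate 1 against 65.4 and 83.9 CPM in replicates 2 and 3, and 73.8 to 184 CPM in the controls. Arc, an immediate early gene best known from neurons, had 834 CPM in BRD4-deleted replicate 1 and 13.3 to 59.7 CPM in the other 5 libraries. Eln, Nqo1 and Arc were chosen after their values were seen.

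The grouping of the libraries was compared with the other splits of 3 against 3, of which there are 10 with the real one. With 10 splits no share under 0.05 can be reached. Every other split mixes control and BRD4-deleted libraries, which adds the real difference to the spread within groups. Low gene counts in those splits are therefore built in and say little about chance. By edgeR's quasi-likelihood test the real split gave 1379 genes higher, 1239 lower and 1030 changed at least 2-fold, and was in each case the 1 split with as many, since the highest other split gave 0 genes (at most 698 at an unadjusted p under 0.05). For the gene lists past camera, 8 of the 10 splits gave as many as the real 11, and the highest other split gave 18. The split that put BRD4-deleted replicate 3 with control replicates 1 and 2 gave the 18, so the number of lists by camera with a preset correlation does not tell the real split from the others.

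Genes of G2 and mitosis fell to a median of -2.24, and fewer dividing cells among the BRD4-deleted cells is a candidate explanation. Removing the trend of log2 change on GC content and transcript length left 96.8% of the median (-2.17), and leaving out each BRD4-deleted library left at least 84.9%, which argues against sequence bias and against 1 library as the whole cause. The S phase list was lower as well, with a median of -0.96, as fewer dividing cells would require. Its camera test passed at the preset correlation (adjusted p = 4.50e-06). It did not pass with an estimated correlation (adjusted p = 0.94) or by fry (adjusted p = 0.344). By edgeR's test 3 of its 41 members fell past the threshold, so the list leaves that explanation open. The S phase median was lowest in BRD4-deleted replicate 1 (-2.73, against -0.70 and -0.42 in replicates 2 and 3), and without that library it was -0.55. Whether fewer dividing cells would follow from loss of BRD4 or from infection and sorting was not tested, since the labels do not say what the control cells received.

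BRD4-deleted replicate 1 stood apart from replicates 2 and 3. GC content and transcript length explained 0.861% of the variance of that difference over genes, and over genes the difference from replicate 3 correlated with the response in replicate 2 at r = -0.0217 (-0.0873 with replicates 2 and 3 exchanged; genes are not independent replicates). The first value argues against sequence bias as the whole cause. A larger size of the same response alone would have given a positive correlation, which was not seen. The G2 and S phase lists did fall further in this library. On the first principal component, which parted the groups, it lay at 67.65 against 32.3 and 28.3 for replicates 2 and 3. What replicates 2 and 3 share enters the correlation with opposite signs and lowers it. The correlation therefore cannot tell whether a larger response is part of the difference. RNA from other cell types may add to it and stays open, though the cells had been sorted. The highest median differences of marker lists were 0.86 (epithelial), 0.77 (adipocyte) and 0.69 (cartilage and bone). Macrophage (-0.88) and skeletal muscle (-0.27) markers were lower. Against the control mean the median of the 6 epithelial genes was 1.45, -0.01 and 1.18 in BRD4-deleted replicates 1, 2 and 3. Replicate 3 was thus nearly as high as replicate 1. Of these epithelial genes, Krt19 had 8.29 CPM in replicate 1 and 8.57 and 10.6 CPM in replicates 2 and 3. Krt19, Perp and Dsp of that list were also above 10 CPM in the mean of the controls.

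The immediate early genes were part of that difference: 26 of 31 were higher in BRD4-deleted replicate 1 than in both other replicates, with a median difference of 1.29. Stress of that culture during handling may be one source. If it were of the heat shock kind, a list of 12 heat shock genes would be expected to rise by at least 1. Their median difference was -0.074, and 5 of 12 were higher in BRD4-deleted replicate 1 than in both other replicates. The standard error of that median, 0.338, is a spread over the 12 genes, which are not independent replicates. A median rise of 1 was thus not seen, while a smaller rise cannot be told from none. The test leaves other kinds of handling or stimulation open, because those need not induce heat shock genes.

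Igf2 and H19, which share an imprinted region, both rose, and cells from another body region in the BRD4-deleted cultures could give such a difference. Of 16 tested Hox genes, whose levels mark position along the body, 0% passed edgeR's quasi-likelihood test, 0 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0. Their log2 changes ran from -1.29 to 0.86 around a median of 0.007. The list held 32 Hox genes, and the tested ones had a median of 4.59 CPM in the controls. A shared shift of the Hox genes was thus not seen. With 3 libraries per group and levels this low, changes could be missed, so cells from another body region stay open. Whether the rise follows from loss of BRD4 or from a difference between cultures that Hox genes do not show was not tested, because each culture's origin is not given in the labels.

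A hypothesis that longer genes fall more after loss of BRD4 was tested across 12492 protein-coding genes, which are not independent replicates. The Spearman correlation of log2 change with genomic length was -0.0665, and 177 genes rose and 293 fell in the longest 20% of genes against 302 and 202 in the shortest 20%. Per library it was 0.003, -0.121 and -0.0981 in BRD4-deleted replicates 1, 2 and 3, and after transcript length and GC content were removed 0.0079, -0.0524 and -0.0209. The relation was absent in replicate 1 and weak in the other libraries, so the test leaves the hypothesis undecided.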
